A study of Homo sapiens with 8 samples.

How the data were processed

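The samples were 8 RNA-seq libraries of TMD8, an established human line of activated B cell-like diffuse large B cell lymphoma that stably carried Cas9 and either a control guide RNA or a guide against KLHL14, per the labels. Each kind of cell received DMSO or ibrutinib at 2 nM for 24 h, which gave 4 groups of 2 libraries. Total RNA was made into libraries with a stranded poly(A) kit and sequenced as read pairs, per the labels' protocols. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

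Reads were made with bcl2fastq, aligned with STAR and counted per gene with HTSeq on the human build hg19, per the submitters' processing notes. Versions, settings and annotation are not given in the sources used here. Whether counting used strand is likewise not given, so reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical genes may be lost or misplaced. The deposited table held log2 values for 25066 genes and a row of total reads per library, which was kept out of all tests. Tested on the values, each entry was log2 of a whole number of reads times a factor of its library, with 0 reads listed at 0. Within a tolerance of 6e-04 on the log2 scale 100% of values were whole reads, 1 read was worth 1.16 to 2.19 on the linear scale, and the recovered reads summed to 99.996% to 100.003% of the totals row. The table had 0 columns of other samples. Depth ran from 12333876 to 23467110 reads, and deeper libraries give less counting error for low genes.

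The 12533 genes whose mean over all libraries was at least 4.20 were kept. They held at least 99.9% of the reads of each library, and 0 of them had a library without reads, so no pseudocount entered. Log2 values were fitted with 4 group means in limma 3.58.1 under R 4.3.3, with the variance prior following the mean (limma-trend; 4 residual and 14.9 prior degrees of freedom). Contrasts were ibrutinib against DMSO with either guide and averaged over guides, sgKLHL14 against sgCTRL in either treatment, and the difference between the ibrutinib responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the deposited scale. The size of the whole response was tested with fry, the rotation test of limma.

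Gene lists for 28 pathways, cell states and other cell types were fixed before the data were examined, and 27 were tested, since 0 of the 13 genes of a mitochondrial list were found in the table. The tested lists are NF-kB targets, immediate-early genes, MAPK output, STAT3 response, interferon-stimulated genes, B cell receptor components, KLHL14 and cullin-3 partners, S phase, G2/M, ribosome biogenesis, ribosomal proteins, glycolysis, cholesterol synthesis, endoplasmic reticulum stress, amino acid response, p53 targets, FOXO-linked genes, germinal centre, plasma cell, MHC class II, MHC class I, adhesion, BCL2 family, histones, and markers of T cells, myeloid cells, and epithelium and fibroblasts. Camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over lists within a contrast, and was repeated with a correlation estimated per list. Some genes belong to more than 1 list. The groups, contrasts, alternatives and rule for named genes were fixed at the same time. The rule takes KLHL14 and BTK, the 8 highest and 8 lowest log2 changes per contrast among called genes whose groups do not overlap and that have an official symbol (814 of the kept genes have none), and up to 4 members per list with the smallest p. With fewer than 5 calls it takes the 5 smallest p. Other list members are named where 5 or fewer moved in a direction and were chosen after their values were seen. Some members of the lists are not reported here by name. Symbols are those of the table, among them IGJ (now JCHAIN), HNRPLL (HNRNPLL), AMICA1 (JAML), C1orf38 (THEMIS2) and MGC29506 (MZB1). Entries in the RefSeq gene list of GRCh38.p14 were found for 85.0% of all genes, and that list served only for names and for which genes neighbour each other.

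The fit was tested in 20 runs on 12533 genes simulated independently at these depths, 200 of them changed. False calls made up 6.02% of calls for ibrutinib with sgCTRL, 4.11% with sgKLHL14, 3.62% for the guides in DMSO, 7.53% for the guides in ibrutinib and 3.80% for the difference in response. With equal depths the guides in ibrutinib gave 4.75%. In the same order 1.5-fold changes were recovered in 80.7%, 80.4%, 79.9%, 80.4% and 67.3% of cases and 2-fold changes in 91.9%, 91.6%, 91.3%, 92.8% and 84.6%. Camera called 4.44% of lists without effect in the difference in response (0.560% with estimated correlation) and a list changed 1.25-fold in 20 of 20 runs. These rates do not cover lists of correlated genes. The first simulation was run after the first fit.

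Alternatives were other filters on low values, no mean-variance trend, a robust prior, quantile and median scaling, library weights, added pseudocounts (1, or as the larger the linear value at the filter's minimum of 4.20), a 1.5-fold minimum, fits of the groups compared alone, the replicate number as a block, each library left out in turn, and other set tests. A fit of recovered reads with voom weights (limma) and reads thinned to the shallowest library were added after seeing the data. Where a library left out leaves a group with 1 library, that library is assumed to vary like the others. Independent overlap of called genes was computed as the product of the counts over 12533.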

Results

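RNA was sequenced from TMD8, a human cell line of activated B cell-like diffuse large B cell lymphoma whose growth depends on chronic B cell receptor signalling. The cells expressed Cas9 with either a control guide RNA (sgCTRL) or a guide against KLHL14 (sgKLHL14), an adaptor of a cullin-3 ubiquitin ligase, and were given solvent (DMSO) or 2 nM ibrutinib, a covalent inhibitor of Bruton tyrosine kinase (BTK), for 24 h. Each of the 4 groups held 2 libraries. The deposited totals were 13497206 and 23152352 reads for sgCTRL in DMSO, 23467110 and 22189713 for sgKLHL14 in DMSO, 16520319 and 13331861 for sgCTRL in ibrutinib, and 16843591 and 12333876 for sgKLHL14 in ibrutinib. Libraries of 1 group correlated across genes at 0.994 to 0.996 and had an SD of 0.16 to 0.18 (log2 scale, root mean square over genes). They differed by more than sampling noise, with a chi-square per degree of freedom of 4.13 and 2.18 in sgCTRL (DMSO, ibrutinib) and 7.89 and 3.76 in sgKLHL14, so none was taken for a copy of another. The first principal component held 64.8% of the variance and separated treatments, with the DMSO libraries at -25.2 to -23.8 and the ibrutinib libraries at 23.4 to 26.6. The second held 11.3% and separated the guides, with sgCTRL at 7.07 to 13.2 and sgKLHL14 at -11.6 to -6.71.

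KLHL14 mRNA was not lower in the libraries labelled sgKLHL14. Its log2 level was 12.07 and 12.06 in the sgCTRL DMSO libraries (12.06 ± 0.011, SD, n = 2), 12.19 and 12.33 in sgKLHL14 DMSO (12.26 ± 0.098), 12.30 and 12.30 in sgCTRL ibrutinib (12.30 ± 0.0014), and 13.16 and 13.16 in sgKLHL14 ibrutinib (13.16 ± 0.0049). These levels rested on 2147, 3660, 4001, 4225, 3082, 2494, 5615 and 4191 reads in that order. In ibrutinib, KLHL14 was higher with sgKLHL14 by 0.86 (SE 0.060, limma adjusted p = 2.61e-08), and in DMSO the difference of 0.20 (SE 0.060) did not pass (adjusted p = 0.107). Ibrutinib raised KLHL14 by 0.24 with sgCTRL (SE 0.060, adjusted p = 0.00418) and by 0.90 with sgKLHL14 (adjusted p = 9.88e-10). A guide RNA with Cas9 makes small insertions or deletions, which a read count per gene does not show, so these values do not check the genotype. Directions by guide are therefore given for the libraries labelled sgKLHL14.

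BTK, the kinase that ibrutinib binds, had mean log2 levels of 13.77 in DMSO and 13.94 in ibrutinib with sgCTRL, and of 13.75 and 14.03 with sgKLHL14 (n = 2 each). Its mRNA rose with ibrutinib by 0.17 with sgCTRL (SE 0.057, limma adjusted p = 0.0282) and by 0.28 with sgKLHL14 (adjusted p = 0.000585). It did not differ by guide in DMSO (-0.024, adjusted p = 0.893) or in ibrutinib (0.092, adjusted p = 0.560), nor did its response (0.12, adjusted p = 0.936). The DMSO difference was 0.0065 without sgCTRL and 0.005 without sgKLHL14 DMSO replicate 1. The call in sgCTRL ended without sgCTRL DMSO replicate 2 (adjusted p = 0.143), without sgCTRL ibrutinib replicate 1 (0.105) and without replicate 2 (0.226). It also ended without the level filter (0.0633) and without the variance trend (0.0909).

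**Figure D1:**
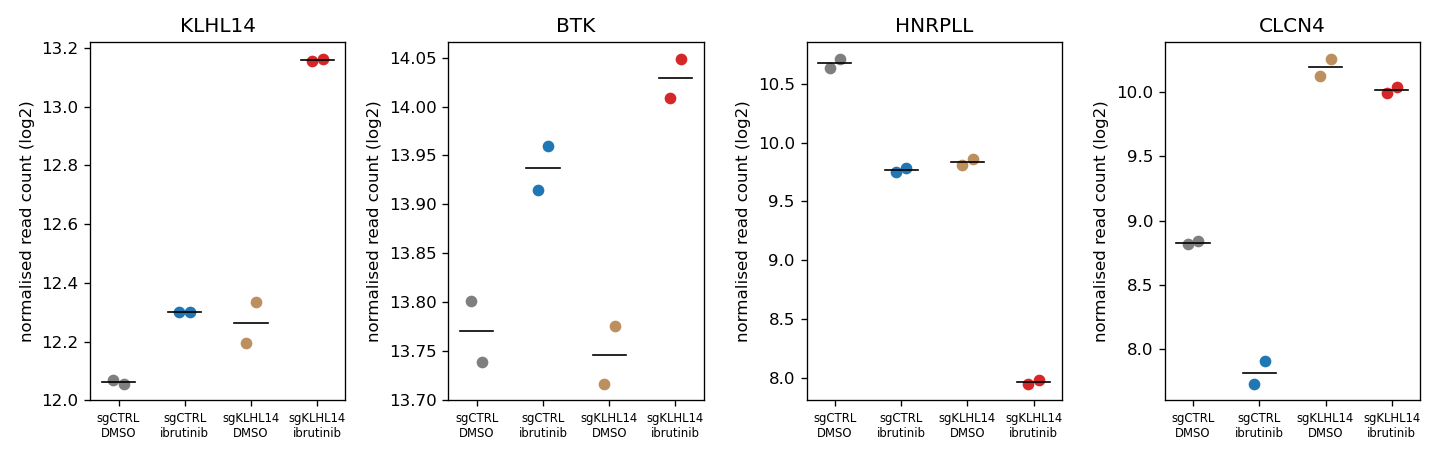
Log2 level (vertical axis) of KLHL14, BTK, HNRPLL and CLCN4 in each of the 8 libraries by group, with dots for libraries and bars for group means. KLHL14 lies at 13.16 in both sgKLHL14 ibrutinib libraries and between 12.06 and 12.33 in the other 6.

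The first comparison asks what the BTK inhibitor changed in cells with the control guide. Ibrutinib lowered NF-kB target genes, amino acid response genes and G2/M genes, and raised interferon-stimulated genes. Components of the B cell receptor also rose as a list, a call lost with an estimated correlation (adjusted p = 0.0946). The largest gains were TAS1R3 (4.91), AFF2 (3.67), VPREB3 (3.27) and NLRP7 (2.97) on the log2 scale, followed by IGJ (2.83), SYNPO2 (2.76), LDB3 (2.63) and ABLIM1 (2.41), where TAS1R3 is a taste receptor subunit, VPREB3 a protein linked to the pre-B cell receptor, IGJ the joining chain of polymeric antibodies, and SYNPO2, LDB3 and ABLIM1 actin-associated proteins. The largest losses were TPRG1 (-4.35), HHLA2 (-4.31), THRB (-3.88) and CCL22 (-3.55), followed by F5 (-3.44), TNIP3 (-3.12), IL4I1 (-3.11) and EBI3 (-3.05), where HHLA2 is a B7-family ligand, THRB a thyroid hormone receptor, CCL22 a chemokine, F5 coagulation factor V and EBI3 a cytokine subunit. Standard errors of these changes ran from 0.083 for NLRP7 to 0.52 for TAS1R3, and their limma adjusted p-values from 8.92e-15 for NLRP7 to 2.63e-06 for LDB3. Counts behind the extremes were low, with 1 and 7 reads of TAS1R3 in DMSO and 3 and 2 reads of TPRG1 in ibrutinib. In all, 4403 of 12533 genes passed (35.1%), 2270 higher and 2133 lower, of which 286 and 238 changed at least 2-fold. Without sgCTRL ibrutinib replicate 1 or 2 the count was 2933 or 2902. With the larger pseudocount, TAS1R3 was at 2.59, AFF2 at 2.20, TPRG1 at -2.26 and HHLA2 at -2.66.

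Among NF-kB target genes, 23 of the 35 measured fell and PIM1, a kinase gene, rose by 0.29 (2 higher and 24 lower adjusted over the list alone; median -0.48, camera adjusted p = 4.08e-13). The call held with an estimated correlation (adjusted p = 0.0168). The decreases included CCL22 (-3.55), EBI3 (-3.05) and IL10 (-2.50) and TNFAIP3 (-0.87) and CFLAR (-0.82), a feedback inhibitor of NF-kB and an inhibitor of death receptor signalling. Immediate-early and B cell receptor-induced genes fell in 13 of 19 cases, also 13 adjusted over the list alone (median -0.42, camera adjusted p = 4.52e-07; adjusted p = 0.103 with estimated correlation). They included the transcription factors EGR2 (-2.29), ATF3 (-1.28) and JUN (-1.09) and the early response gene IER3 (-1.58). Of 19 STAT3 response genes, 9 fell, among them CD274 (-1.60) and BATF (-1.12), which encode an immune checkpoint ligand and a transcription factor, and PIM1 (0.29), IL10RA (0.66), GZMB (0.94) and LGALS3BP (1.70) rose (4 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.270 with estimated correlation). The 10 measured MAPK output genes did not move as a group (median -0.058, camera adjusted p = 0.415). In that list ETV4 (-1.39), ETV5 (-1.15) and PHLDA1 (-0.61) fell, and DUSP5 (0.76) and EPHA4 (0.50), a phosphatase acting on ERK and an ephrin receptor, rose (2 higher and 3 lower adjusted over the list alone).

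Amino acid response genes, which the transcription factor ATF4 induces, fell in 22 of 26 cases, and SLC7A1, a cationic amino acid carrier, rose by 0.21 (1 higher and 23 lower adjusted over the list alone; median -0.98, camera adjusted p = 3.85e-21, held with an estimated correlation, adjusted p = 0.00538). The decreases included CTH (-2.42), WARS (-1.50) and ASNS (-1.45), which act in cysteine synthesis, tryptophanyl-tRNA charging and asparagine synthesis, and ATF5 (-1.31). Cell cycle genes fell by smaller amounts. Of 28 G2/M genes 23 fell, 24 adjusted over the list alone, among them CCNA2 (-0.46) and TPX2 (-0.38) (median -0.28, camera adjusted p = 3.94e-09, held with an estimated correlation, adjusted p = 0.0174). Of 28 S phase genes 16 fell, among them CHAF1B (-0.58) and MCM6 (-0.43), while E2F2 (0.85), CCNE2 (0.42) and E2F1 (0.21) rose (3 higher and 18 lower adjusted over the list alone; median -0.21, camera adjusted p = 0.000130; adjusted p = 0.172 with estimated correlation). MYC-linked ribosome biogenesis genes fell in 17 of 30 cases, 18 adjusted over the list alone, with PA2G4 (-0.52) and NOLC1 (-0.44) as examples (median -0.23, camera adjusted p = 1.64e-06; adjusted p = 0.110 with estimated correlation). Replication-dependent histone genes rose in 11 of 13 cases, 12 adjusted over the list alone (median 0.77, camera adjusted p = 4.47e-07; adjusted p = 0.103 with estimated correlation). HIST1H1C rose by 0.87. Near-identical copies share reads and a poly(A) kit misses histone mRNA without that tail, so all histone levels are uncertain. SLC7A1 and E2F1 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0728 to 0.135). E2F1 and CCNE2 lost it without replicate 2 (0.0667 to 0.0748). SLC7A1 and E2F1 lost it without sgCTRL ibrutinib replicate 1 (0.0873 to 0.205). SLC7A1, CCNE2 and E2F1 lost it without replicate 2 (0.0706 to 0.116). SLC7A1 and E2F1 did not pass without the level filter (0.0610 to 0.0650) and without the variance trend (0.0608 to 0.0887), nor did CCNE2 with thinned reads (0.118). With thinned reads, CCNE2 was at 0.27.

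Glycolysis and hypoxia genes fell in 11 of 27 cases, including PDK1 (-0.86), VEGFA (-0.63) and LDHA (-0.47), and SLC2A3 (1.21), SLC2A1 (0.42) and PFKP (0.21), a pair of glucose carriers and a phosphofructokinase, rose (3 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.0149; adjusted p = 0.244 with estimated correlation). Cholesterol biosynthesis genes rose in 9 of 23 cases, 12 adjusted over the list alone, with LSS (0.55) and HMGCS1 (0.42) among them (camera adjusted p = 0.000497; adjusted p = 0.228 with estimated correlation). Of 22 endoplasmic reticulum stress genes 11 rose, among them the secretory chaperone genes DERL3 (1.37) and PDIA4 (0.64), and EDEM1 (-0.97), HERPUD1 (-0.55), SEL1L (-0.44) and PDIA6 (-0.25) fell (13 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0426; adjusted p = 0.201 with estimated correlation). Ribosomal protein genes rose in 8 of 32 cases, also 8 adjusted over the list alone, with RPL3 (0.36) as an example (median 0.10, camera adjusted p = 0.0102; adjusted p = 0.552 with estimated correlation), and reads of their pseudogenes make single values uncertain. Of 20 FOXO and quiescence-linked genes 13 rose, including CCR7 (0.88), CXCR4 (0.70) and BCL2L11 (0.53) (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000512; adjusted p = 0.110 with estimated correlation). The p53 target list did not pass (median 0.092, camera adjusted p = 0.0854), with 7 of 24 genes higher and SESN2 (-1.88), which ATF4 also induces, lower (7 higher and 1 lower adjusted over the list alone). The endoplasmic reticulum stress list lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0588). PFKP lost it without replicate 2 (0.193). PFKP, PDIA6, and the endoplasmic reticulum stress and ribosomal protein lists lost it without sgCTRL ibrutinib replicate 1 (0.0507 to 0.0586). PFKP and the endoplasmic reticulum stress list lost it without replicate 2 (0.0753 to 0.146). PFKP was at 0.12 without sgCTRL DMSO replicate 2. PFKP did not pass without the level filter (0.0598) and without the variance trend (0.0957). The p53 target list passed without the level filter (0.0341).

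Interferon-stimulated genes rose in 28 of 31 cases, 30 adjusted over the list alone (median 1.07, camera adjusted p = 1.45e-20, held with an estimated correlation, adjusted p = 0.00538). They included the antiviral genes XAF1 (1.62), OAS1 (1.59), OAS2 (1.22) and MX1 (1.07). B cell receptor components rose in 20 of 33 cases, among them the receptor chain CD79B (1.24), the adaptor DAPP1 (0.99) and the inhibitory receptors FCGR2B (0.83) and CD72 (0.70), and the kinase genes FYN (-0.78) and LYN (-0.21) fell (22 higher and 3 lower adjusted over the list alone; median 0.27, camera adjusted p = 2.00e-06; adjusted p = 0.0946 with estimated correlation). MHC class I and antigen processing genes rose in 6 of 15 cases, also 6 adjusted over the list alone, including PSMB8 (0.68) and NLRC5 (0.49) (median 0.14, camera adjusted p = 0.0102; adjusted p = 0.244 with estimated correlation). The MHC class II list did not pass (median 0.036, camera adjusted p = 0.237), with 7 of 17 genes higher and HLA-DQB1 (-0.89), HLA-DQA1 (-0.34) and HLA-DRB5 (-0.26) lower (7 higher and 3 lower adjusted over the list alone), and single HLA genes are uncertain because related loci and alleles share reads. HLA-DRB5 and HLA-DQA1 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0968 to 0.101). HLA-DQB1 and HLA-DQA1 lost it without replicate 2 (0.0648 to 0.162). HLA-DQA1, HLA-DRB5 and LYN lost it without sgCTRL ibrutinib replicate 1 (0.0904 to 0.133). HLA-DQA1, LYN and HLA-DQB1 lost it without replicate 2 (0.0566 to 0.0796). MHC class I genes had a median of 0.090 without sgCTRL DMSO replicate 2. HLA-DQA1 and HLA-DQB1 did not pass without the level filter (0.0528 to 0.0616), nor did HLA-DQB1 with thinned reads (0.0690).

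Lists of B cell state did not pass as groups, although many members changed. Of 20 plasma cell genes 11 rose and 6 fell, the latter with SLAMF7 (-1.58) and IRF4 (-0.88) (12 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.206), and of 20 germinal centre genes 9 rose, with STAP1 (1.63) and S1PR2 (1.03), while LMO2 (-0.88), RGS13 (-0.61), MEF2C (-0.28) and DENND3 (-0.25) fell (9 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0920). Of 22 adhesion and migration receptors 8 rose and 9 fell, the latter with ITGAX (-1.44) and CD58 (-1.39) (8 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.205). In the BCL2 family BCL2L11 (0.53), MCL1 (0.35), BBC3 (0.34) and BAX (0.33) rose and PMAIP1 (-0.86), BCL2L2 (-0.58), BCL2A1 (-0.50), BCL2L1 (-0.44) and BID (-0.42) fell, out of 14 measured (4 higher and 5 lower adjusted over the list alone), and the median of 0.0078 differed in sign from the mean of -0.071 and from the test (camera adjusted p = 0.466), and turned to -0.025 with quantile scaling, -0.013 without sgCTRL DMSO replicate 1 and -0.010 without sgCTRL ibrutinib replicate 2. Among 15 KLHL14 and cullin-3 partners KLHL24 (0.55), KLHL14 (0.24), KLHL9 (0.23) and TOR1AIP1 (0.20) rose and KLHL6 (-0.79) fell (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.296). TOR1AIP1, BBC3 and KLHL9 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.102 to 0.274). BBC3 lost it without replicate 2 (0.163). TOR1AIP1, MEF2C, BBC3 and KLHL9 lost it without sgCTRL ibrutinib replicate 1 (0.0645 to 0.360). KLHL9 and TOR1AIP1 lost it without replicate 2 (0.123 to 0.124). BBC3 lost it without sgKLHL14 ibrutinib replicate 1 (0.0504). BBC3 was at 0.21 without sgCTRL ibrutinib replicate 1. BBC3 and KLHL9 did not pass without the level filter (0.121 to 0.125), nor did TOR1AIP1, BBC3 and KLHL9 without the variance trend (0.0548 to 0.150). BBC3 did not pass with quantile scaling (0.102) and with median scaling (0.0501), nor did KLHL9 with voom (0.0555). The germinal centre list passed without the level filter (0.0301).

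Few markers of other cell types were expressed. Of 15 T cell markers 3 passed the level filter, led by CD5 at a mean log2 level of 8.33, which some B cell lymphomas express, and CD5 (0.73) rose (camera adjusted p = 0.0925; 2 higher and 0 lower adjusted over the list alone). Of 15 myeloid markers 2 passed, with FCGR1A (1.64) higher and VCAN (-1.53) lower at a highest level of 4.54 (1 higher and 1 lower adjusted over the list alone; median 0.057, camera adjusted p = 0.955). That list turned direction without sgCTRL DMSO replicate 2 (-0.062), without sgCTRL ibrutinib replicate 2 (-0.29), and by its test alone without sgKLHL14 ibrutinib replicate 1 or 2 (median 0.057), and its median was -0.028 with quantile scaling. Of 14 epithelial and fibroblast markers 7 passed, led by CDH1 at 10.25, with DCN (1.94) and COL1A1 (1.06) higher and KRT8 (-0.47) lower (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.354). VCAN and KRT8 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0869 to 0.178). KRT8 and VCAN lost it without sgCTRL ibrutinib replicate 1 (0.0888 to 0.103). FCGR1A lost it without replicate 2 (0.151). VCAN and FCGR1A did not pass without the level filter (0.0525 to 0.120), nor did VCAN without the variance trend (0.0938). With the larger pseudocount, FCGR1A was at 0.93 and VCAN at -0.92.

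The second comparison asks the same in the libraries labelled sgKLHL14. Ibrutinib again lowered NF-kB targets, amino acid response genes and G2/M genes and raised interferon-stimulated genes. The largest gains were TAS1R3 (4.35), AFF2 (2.91), SYNPO2 (2.87) and FNDC5 (2.78), then NLRP7 (2.74), IGJ (2.58), KCNH2 (2.52) and ABLIM1 (2.51), where FNDC5 is the precursor of irisin and KCNH2 a potassium channel. The largest losses were TPRG1 (-4.53), CCL22 (-4.19), F5 (-4.00) and HHLA2 (-3.98), then EBI3 (-3.58), INHBC (-3.12), THRB (-3.10) and TNIP3 (-2.94), where INHBC is an inhibin subunit. Standard errors ran from 0.083 for NLRP7 to 0.52 for TAS1R3, and limma adjusted p-values from 4.02e-14 for NLRP7 to 1.44e-05 for FNDC5. In all, 4924 of 12533 genes passed (39.3%), 2489 higher and 2435 lower, of which 302 and 218 changed at least 2-fold. With the larger pseudocount, TAS1R3 was at 2.74, FNDC5 at 1.55, TPRG1 at -2.25, F5 at -2.59, HHLA2 at -2.59 and INHBC at -1.76.

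NF-kB targets fell in 23 of 35 cases, with IL10 (-2.51) and CFLAR (-0.81) as examples, and NFKBIZ (0.15) and PIM1 (0.20) rose (3 higher and 24 lower adjusted over the list alone; median -0.41, camera adjusted p = 6.26e-10). Amino acid response genes fell in 23 of 26 cases, with CTH (-2.28), CHAC1 (-2.17), ASNS (-1.36) and WARS (-1.15) (1 higher and 24 lower adjusted over the list alone; median -0.91, camera adjusted p = 9.86e-19). G2/M genes fell in 27 of 28 cases, with DLGAP5 (-0.56) and CCNA2 (-0.55) (28 adjusted over the list alone; median -0.46, camera adjusted p = 1.11e-15), and interferon-stimulated genes rose in 27 of 31, with OAS1 (1.60), OAS2 (1.12) and STAT2 (0.93) (28 adjusted over the list alone; median 0.89, camera adjusted p = 9.79e-16). These lists held with an estimated correlation (adjusted p = 0.00770 to 0.0228). S phase genes fell in 24 of 28 cases, with MCM2 (-0.63) and MCM6 (-0.60), and E2F2 (0.62) rose (1 higher and 25 lower adjusted over the list alone; median -0.41, camera adjusted p = 9.61e-11; adjusted p = 0.0614 with estimated correlation). Ribosome biogenesis genes fell in 23 of 30 cases, 25 adjusted over the list alone (camera adjusted p = 1.23e-07; adjusted p = 0.0984 with estimated correlation), and immediate-early genes in 11 of 19, with EGR2 (-2.88), while CD69 (0.61) rose (1 higher and 12 lower adjusted over the list alone; camera adjusted p = 3.66e-05; adjusted p = 0.114 with estimated correlation). NFKBIZ lost the call without sgCTRL ibrutinib replicate 1 (adjusted p = 0.0822) and without replicate 2 (0.0821). CD69 and NFKBIZ lost it without sgKLHL14 DMSO replicate 1 (0.0688 to 0.158). PIM1, CD69 and NFKBIZ lost it without replicate 2 (0.05003 to 0.0811). CD69, NFKBIZ and PIM1 lost it without sgKLHL14 ibrutinib replicate 1 (0.0781 to 0.156). NFKBIZ lost it without replicate 2 (0.174). CD69 and NFKBIZ did not pass without the level filter (0.0796 to 0.0830), nor did CD69, NFKBIZ and PIM1 without the variance trend (0.0530 to 0.125). NFKBIZ did not pass with library weights (0.0624) and with the compared groups fitted alone (0.0954).

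B cell receptor components rose in 22 of 33 cases, with CD79B (1.15) as the example, and FYN (-0.77) and PTPN6 (-0.23) fell (22 higher and 2 lower adjusted over the list alone; camera adjusted p = 2.86e-07; adjusted p = 0.0614 with estimated correlation). FOXO-linked genes rose in 14 of 20 cases (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000216; adjusted p = 0.0996 with estimated correlation). Plasma cell genes rose in 13 of 20 cases, with CD27 (2.00) and POU2AF1 (0.82), a receptor of plasmablasts and a coactivator, and SLAMF7 (-1.06), CAV1 (-1.02), IRF4 (-0.57) and TXNDC5 (-0.33) fell (13 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00640; adjusted p = 0.106 with estimated correlation). Endoplasmic reticulum stress genes rose in 12 of 22 cases and EDEM1 (-0.79), HERPUD1 (-0.36) and SEL1L (-0.25) fell (12 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00450; adjusted p = 0.0996 with estimated correlation). MHC class I genes rose in 8 of 15 cases, also 8 adjusted over the list alone (camera adjusted p = 0.00157; adjusted p = 0.195 with estimated correlation), and histone genes in 9 of 13, with H2AFX (-0.34) lower (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.47e-05; adjusted p = 0.114 with estimated correlation). Passing by smaller margins were glycolysis (median -0.16, camera adjusted p = 0.0259; adjusted p = 0.262 with estimated correlation), cholesterol (median 0.11, camera adjusted p = 0.0265; adjusted p = 0.341 with estimated correlation), MHC class II (median 0.14, camera adjusted p = 0.0348; adjusted p = 0.263 with estimated correlation) and ribosomal protein genes (median 0.095, camera adjusted p = 0.0496; adjusted p = 0.707 with estimated correlation). The ribosomal protein list lost the call without sgCTRL ibrutinib replicate 1 (adjusted p = 0.0806) and without replicate 2 (0.0811). PTPN6 and H2AFX lost it without sgKLHL14 DMSO replicate 1 (0.102 to 0.209). SEL1L and the ribosomal protein, cholesterol and MHC class II lists lost it without replicate 2 (0.0862 to 0.807). The cholesterol and ribosomal protein lists lost it without sgKLHL14 ibrutinib replicate 1 (0.0765 to 0.543). H2AFX lost it without replicate 2 (0.372). SEL1L was at -0.14 without sgKLHL14 DMSO replicate 2. H2AFX was at -0.52 without sgKLHL14 ibrutinib replicate 1 and -0.16 without replicate 2. Cholesterol genes had a median of 0.068 without sgKLHL14 DMSO replicate 2 and 0.068 without sgKLHL14 ibrutinib replicate 1. MHC class II genes had a median of 0.22 without sgKLHL14 DMSO replicate 1 and 0.074 without replicate 2. Ribosomal protein genes had a median of 0.17 without sgKLHL14 DMSO replicate 1, 0.021 without replicate 2, 0.024 without sgKLHL14 ibrutinib replicate 1 and 0.16 without replicate 2. PTPN6 and H2AFX did not pass without the level filter (0.0569 to 0.122), nor did H2AFX, PTPN6 and SEL1L without the variance trend (0.0670 to 0.137).

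The responses with either guide ran closely in parallel across genes. Of the genes that rose, 1753 rose with both guides, where independent lists of these sizes would share 450.8, and of those that fell 1727 were shared, against 414.4. Log2 changes correlated across the 12533 genes at a Pearson coefficient of 0.853 and a Spearman coefficient of 0.814, and genes are not independent replicates. Of the 5846 genes called with either guide 97.6% had the same sign. The comparisons share no library.

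**Figure D2:**
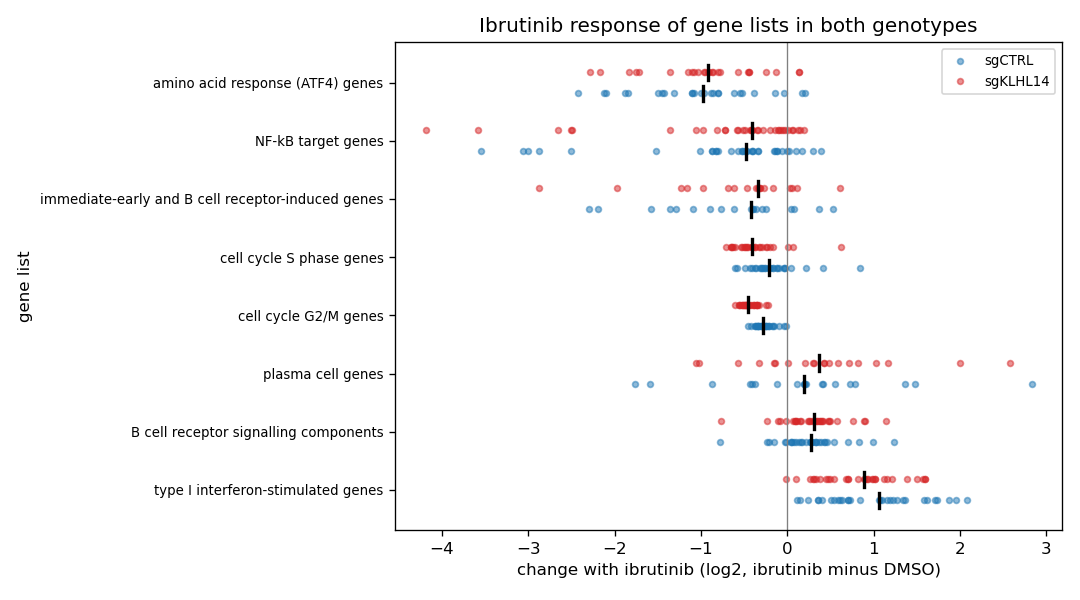
Log2 change with ibrutinib (horizontal axis) of the measured genes of 8 lists with sgCTRL (blue) and sgKLHL14 (red), each dot a gene and each bar the list median. Interferon-stimulated genes have medians of 1.07 and 0.89 and amino acid response genes of -0.98 and -0.91 in sgCTRL and sgKLHL14.

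**Figure D3:**
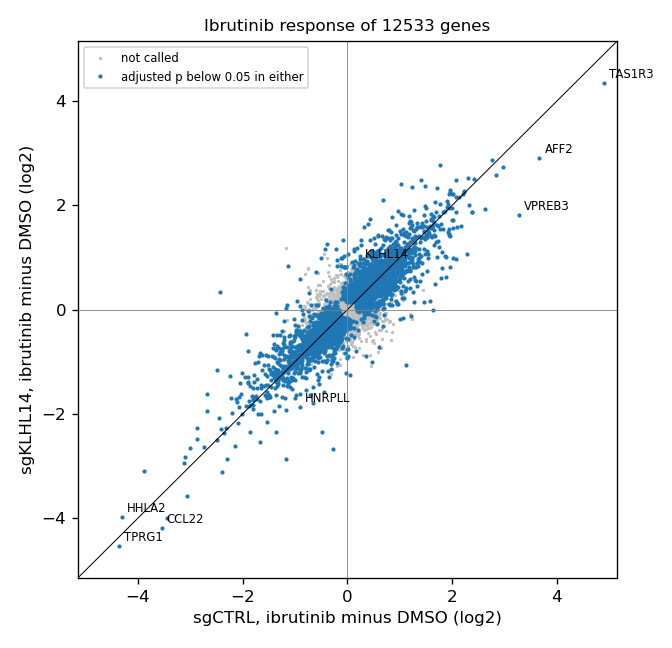
Log2 change with ibrutinib in sgCTRL (horizontal axis) against sgKLHL14 (vertical axis) for each of 12533 genes, with the 5846 genes called with either guide in blue. The points follow the diagonal, at a Pearson coefficient of 0.853 across genes.

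The third comparison asks what differed between the guides without inhibitor. The libraries labelled sgKLHL14 held more mRNA of VPREB3 and of the lymphocyte receptor SLAMF6. MHC class II genes were lower as a list, with 7 of 17 passing singly, a call lost with an estimated correlation (adjusted p = 0.170). The largest gains were VPREB3 (2.70), ADAMTS17 (2.64), AFF2 (1.80) and CCL17 (1.57), then CLCN4 (1.37), ERV3 (1.36), SLAMF6 (1.26) and OLFML2A (1.12), where CCL17 is a chemokine, CLCN4 a chloride and proton exchanger and ERV3 an endogenous retroviral gene whose level is uncertain because related copies can share reads. The largest losses were FGFBP2 (-1.84), LILRA4 (-1.53), AMICA1 (-1.24) and ABCD2 (-1.04), then FILIP1L (-1.01), ITGAX (-0.96), KLHDC7B (-0.95) and ZC3H12C (-0.91), where LILRA4 and AMICA1 are receptors of immune cells and ITGAX is an integrin chain. Standard errors ran from 0.087 for SLAMF6 to 0.53 for ADAMTS17, and limma adjusted p-values from 7.58e-08 for CLCN4 to 0.0417 for FGFBP2. In all, 206 of 12533 genes passed (1.64%), 98 higher and 108 lower. The count was 64 without sgCTRL DMSO replicate 1, 76 without sgKLHL14 DMSO replicate 1 and 530 without replicate 2. It was 47 without the level filter and 25 without the variance trend. KLHDC7B, ZC3H12C, FGFBP2, LILRA4 and ABCD2 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0744 to 0.417). ZC3H12C, ADAMTS17, CCL17, FGFBP2 and ABCD2 lost it without replicate 2 (0.0586 to 0.110). ADAMTS17, CCL17, FGFBP2, ABCD2 and ZC3H12C lost it without sgKLHL14 DMSO replicate 1 (0.0982 to 0.341). FGFBP2 lost it without replicate 2 (0.0765). ADAMTS17 was at 1.45 without sgCTRL DMSO replicate 2. LILRA4, ABCD2, KLHDC7B, ZC3H12C, ADAMTS17, CCL17 and FGFBP2 did not pass without the level filter (0.104 to 0.258). ZC3H12C, VPREB3, ADAMTS17, FGFBP2, LILRA4 and KLHDC7B did not pass without the variance trend (0.0524 to 0.264). FGFBP2 did not pass with library weights (0.0749), nor did ZC3H12C and FGFBP2 with thinned reads (0.0732 to 0.150). With the larger pseudocount, VPREB3 was at 1.78, ADAMTS17 at 1.03, AFF2 at 0.81, CCL17 at 0.99 and FGFBP2 at -1.15. With thinned reads, ABCD2 was at -1.67.

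MHC class II genes, which present peptides to helper T cells, were lower in 7 of 17 cases, with HLA-DQA2 (-0.65), HLA-DQA1 (-0.62), HLA-DRB5 (-0.47) and HLA-DMA (-0.36) (12 lower adjusted over the list alone; median -0.26, camera adjusted p = 2.00e-11; adjusted p = 0.170 with estimated correlation). Single HLA genes are uncertain because loci and alleles share reads. In the plasma cell list XBP1 (0.38), SDC1 (0.54), MGC29506 (0.32) and SLAMF7 (0.35) were higher, out of 20 (6 higher and 2 lower adjusted over the list alone; median 0.12, camera adjusted p = 0.00181; adjusted p = 0.279 with estimated correlation). In the FOXO-linked list KLHL24 (-0.39) and BCL2L11 (-0.30) were lower and CXCR4 (0.51) higher (3 higher and 4 lower adjusted over the list alone; median -0.16, camera adjusted p = 0.0238; adjusted p = 0.383 with estimated correlation). In the amino acid response list AARS (0.25) was higher and SLC7A11 (-0.34) lower (3 higher and 1 lower adjusted over the list alone; median 0.082, camera adjusted p = 0.0158; adjusted p = 0.279 with estimated correlation). Among ribosome biogenesis genes SRM (0.29) was higher (3 higher and 0 lower adjusted over the list alone; median 0.074, camera adjusted p = 7.64e-05; adjusted p = 0.336 with estimated correlation). All genes named here but HLA-DQA2 and CXCR4 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0506 to 0.402). MGC29506, KLHL24, BCL2L11, AARS, SLC7A11, SRM, SDC1 and the FOXO list lost it without replicate 2 (0.0640 to 0.191). SLC7A11, SRM, SDC1, MGC29506, KLHL24 and AARS lost it without sgCTRL ibrutinib replicate 1 (0.0540 to 0.0759) and without replicate 2 (0.0533 to 0.0755). KLHL24, BCL2L11, AARS, SLC7A11, SRM, HLA-DMA, XBP1, SDC1, MGC29506, SLAMF7 and the FOXO list lost it without sgKLHL14 DMSO replicate 1 (0.0879 to 0.636). SDC1 lost it without replicate 2 (0.0530). KLHL24 and SLC7A11 lost it without sgKLHL14 ibrutinib replicate 1 (0.0543 to 0.0618) and without replicate 2 (0.0533 to 0.0606). KLHL24 was at -0.24 without sgKLHL14 DMSO replicate 1. SLC7A11 was at -0.17 without sgKLHL14 DMSO replicate 1 and -0.51 without replicate 2. Plasma cell genes had a median of 0.18 without sgKLHL14 DMSO replicate 2. Amino acid response genes had a median of 0.048 without sgKLHL14 DMSO replicate 1. Ribosome biogenesis genes had a median of 0.12 without sgKLHL14 DMSO replicate 2. All genes named here but HLA-DRB5 and CXCR4 lost the call without the level filter (0.0812 to 0.308). All genes named here lost the call without the variance trend (0.116 to 0.376). SRM, KLHL24, SLC7A11 and the amino acid response list did not pass with quantile scaling (0.0542 to 0.0742), nor did SRM and MGC29506 with median scaling (0.0543 to 0.0573). SLC7A11, SDC1 and KLHL24 did not pass with library weights (0.0579 to 0.0637), nor did AARS with the compared groups fitted alone (0.0562). SLC7A11 did not pass with a stricter filter (0.0578), nor did SLC7A11 and the amino acid response list with thinned reads (0.0614 to 0.127). With thinned reads, the median was 0.030 for amino acid response genes.

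Small shifts moved whole lists without single genes passing. S phase genes had a median of 0.086 with 0 of 28 called by limma and 0 by voom, 6 at an unadjusted p under 0.05 (camera adjusted p = 0.000325; adjusted p = 0.350 with estimated correlation), and ribosomal protein genes one of 0.081 with 0 of 32 called by limma and 0 by voom, 8 at an unadjusted p under 0.05 (camera adjusted p = 6.22e-05; adjusted p = 0.554 with estimated correlation). Among markers of other cell types, the adhesion gene CDH1 was lower by -0.41 (adjusted p = 0.00351). CDH1 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0679). The ribosomal protein list lost it without sgKLHL14 DMSO replicate 1 (0.444). Ribosomal protein genes had a median of 0.016 without sgKLHL14 DMSO replicate 1 and 0.18 without replicate 2. CDH1 did not pass without the variance trend (0.0797), nor did the ribosomal protein list with quantile scaling (0.0643). With quantile scaling, the median was 0.048 for ribosomal protein genes.

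The fourth comparison asks what differed between the guides under ibrutinib. The libraries labelled sgKLHL14 held more mRNA of plasma cell genes, of KLHL14 and of the ion exchanger CLCN4, and less of G2/M genes and of HNRPLL, an RNA-binding protein that regulates splicing in lymphocytes. The largest gains were ADAMTS17 (2.46), KANK2 (2.33), CLCN4 (2.21) and TG (1.96), then ERV3 (1.72), GLT1D1 (1.53), EPB41L4B (1.44) and CCDC3 (1.42), where TG is the thyroglobulin gene. The largest losses were ENPP3 (-2.36), LILRA4 (-2.09), FGFBP2 (-1.96) and HNRPLL (-1.80), then RAMP2 (-1.45), LRRC25 (-1.37), LAPTM4B (-1.29) and AMICA1 (-1.22), where ENPP3 is a surface enzyme and RAMP2 a receptor-modifying protein. Standard errors ran from 0.083 for HNRPLL to 0.53 for ADAMTS17, and limma adjusted p-values from 2.81e-11 for CLCN4 to 0.0361 for LAPTM4B. In all, 298 of 12533 genes passed (2.38%), 199 higher and 99 lower, of which 25 and 15 differed at least 2-fold. In simulated data at these depths 7.53% of calls in this comparison were false, and voom on recovered reads, chosen after seeing the data, called 255 here (168 higher, 87 lower) and 241 in DMSO, so the counts in DMSO and ibrutinib are not ranked. The count here was 144 without sgCTRL ibrutinib replicate 1, 123 without replicate 2, 171 without sgKLHL14 ibrutinib replicate 1 and 180 without replicate 2. It was 155 without the level filter and 95 without the variance trend. LAPTM4B lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0508). LAPTM4B, GLT1D1, ENPP3, FGFBP2, RAMP2 and LRRC25 lost it without sgCTRL ibrutinib replicate 1 (0.0632 to 0.244). RAMP2, LRRC25, LAPTM4B, ADAMTS17, TG, GLT1D1, EPB41L4B, CCDC3 and ENPP3 lost it without replicate 2 (0.0605 to 0.316). RAMP2, ADAMTS17, GLT1D1 and CCDC3 lost it without sgKLHL14 ibrutinib replicate 1 (0.0906 to 0.227). LAPTM4B, ADAMTS17, TG, GLT1D1, EPB41L4B, ENPP3, FGFBP2, RAMP2 and LRRC25 lost it without replicate 2 (0.0707 to 0.289). ENPP3 was at -1.28 without sgKLHL14 ibrutinib replicate 2. TG, GLT1D1, EPB41L4B, CCDC3, ENPP3, FGFBP2, RAMP2, LRRC25, LAPTM4B and ADAMTS17 did not pass without the level filter (0.0988 to 0.246). LRRC25, LAPTM4B, ADAMTS17, TG, ENPP3 and FGFBP2 did not pass without the variance trend (0.0913 to 0.222). LAPTM4B and FGFBP2 did not pass with quantile scaling (0.0552 to 0.0608), nor did CCDC3, ENPP3 and FGFBP2 with the compared groups fitted alone (0.0798 to 0.0875). FGFBP2 and ENPP3 did not pass with the larger pseudocount (0.0780 to 0.0875), nor did GLT1D1 and CCDC3 with thinned reads (0.0578 to 0.344). LAPTM4B did not pass with voom (0.0987). With the larger pseudocount, ADAMTS17 was at 1.63, TG at 1.26, GLT1D1 at 0.89, EPB41L4B at 0.84, CCDC3 at 0.75, ENPP3 at -0.81, FGFBP2 at -0.77 and RAMP2 at -0.83.

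Plasma cell genes were higher in 9 of 20 cases, including SLAMF7 (0.87), XBP1 (0.76), ELL2 (0.50) and IRF4 (0.43), a surface receptor and regulators of antibody-secreting cells, and IGJ was lower by -0.56 (14 higher and 1 lower adjusted over the list alone; median 0.33, camera adjusted p = 7.26e-14). G2/M genes had a median of -0.14, with 0 of 28 called by limma and 0 by voom over all genes, 10 lower adjusted over the list alone and 15 lower at an unadjusted p under 0.05 (camera adjusted p = 1.09e-09). In the amino acid response list AARS (0.35), TRIB3 (0.30), PSAT1 (0.29) and WARS (0.28) were higher and SLC7A11 (-0.37) lower (9 higher and 1 lower adjusted over the list alone; median 0.16, camera adjusted p = 1.36e-07). These 3 lists held with an estimated correlation (adjusted p = 0.0287 each). S phase genes had a median of -0.13 with 0 of 28 called by limma, 0 by voom and 12 lower at an unadjusted p under 0.05 (camera adjusted p = 1.14e-06; adjusted p = 0.108 with estimated correlation). In the endoplasmic reticulum stress list XBP1 (0.76) was higher (5 higher and 0 lower adjusted over the list alone; camera adjusted p = 6.38e-05; adjusted p = 0.0606 with estimated correlation). TRIB3 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0589) and without replicate 2 (0.0597). IGJ, AARS, TRIB3, PSAT1, WARS and SLC7A11 lost it without sgCTRL ibrutinib replicate 1 (0.0663 to 0.228). TRIB3, PSAT1, WARS, SLC7A11 and IGJ lost it without replicate 2 (0.0650 to 0.520). PSAT1, WARS, SLC7A11, IGJ and TRIB3 lost it without sgKLHL14 ibrutinib replicate 1 (0.0546 to 0.227). TRIB3, WARS, SLC7A11 and IGJ lost it without replicate 2 (0.0686 to 0.110). PSAT1, SLC7A11, IGJ and TRIB3 did not pass without the level filter (0.0535 to 0.189). All genes named here but SLAMF7 and XBP1 lost the call without the variance trend (0.0522 to 0.264). TRIB3 did not pass with the compared groups fitted alone (0.0778), with thinned reads (0.0950) and with voom (0.128).

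Signalling target lists shifted upward. Among NF-kB targets IRF4 (0.43), CD40 (0.31), TNFAIP3 (0.26) and NFKBIZ (0.25) were higher, out of 35 (7 higher and 2 lower adjusted over the list alone; median 0.098, camera adjusted p = 0.00137; adjusted p = 0.108 with estimated correlation). Among 19 immediate-early genes KLF10 (0.72), PHLDA1 (0.69), JUN (0.65), IER3 (0.59) and MYC (0.27) were higher and EGR2 (-0.995) lower (7 higher and 2 lower adjusted over the list alone; median 0.27, camera adjusted p = 0.00131; adjusted p = 0.184 with estimated correlation). Adhesion and migration receptors were higher in 6 of 22 cases, with the integrins ITGAL (0.65) and ITGB1 (0.40) and the chemokine receptor CXCR4 (0.54), and ITGAX (-0.41) and GPR183 (-0.34) were lower (10 higher and 4 lower adjusted over the list alone; median 0.15, camera adjusted p = 6.38e-05; adjusted p = 0.134 with estimated correlation). Interferon-stimulated genes shifted down, with XAF1 (-0.63) and OAS3 (-0.46) lower, out of 31 (0 higher and 3 lower adjusted over the list alone; median -0.11, camera adjusted p = 0.000138; adjusted p = 0.0606 with estimated correlation). MHC class II genes also shifted down, with HLA-DRB5 (-0.48) lower and uncertain by shared reads (0 higher and 6 lower adjusted over the list alone; median -0.17, camera adjusted p = 6.09e-07; adjusted p = 0.0782 with estimated correlation). ITGAX lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0646) and without replicate 2 (0.0645). TNFAIP3, NFKBIZ, MYC, ITGAX, GPR183, OAS3 and CD40 lost it without sgCTRL ibrutinib replicate 1 (0.0820 to 0.343). MYC, ITGAX, CD40, TNFAIP3, NFKBIZ and IER3 lost it without replicate 2 (0.114 to 0.454). ITGAX, GPR183, OAS3, CD40, TNFAIP3, NFKBIZ, IER3 and MYC lost it without sgKLHL14 ibrutinib replicate 1 (0.0588 to 0.202). MYC, ITGAX, GPR183, CD40, TNFAIP3, NFKBIZ and IER3 lost it without replicate 2 (0.0805 to 0.152). NF-kB target genes had a median of 0.056 without sgCTRL ibrutinib replicate 2. Immediate-early genes had a median of 0.13 without sgKLHL14 ibrutinib replicate 1. MYC, ITGAX, CD40, NFKBIZ and IER3 did not pass without the level filter (0.0786 to 0.171). ITGAX, GPR183, OAS3, HLA-DRB5, IRF4, CD40, TNFAIP3, NFKBIZ, IER3, MYC, ITGB1 and CXCR4 did not pass without the variance trend (0.0522 to 0.258). ITGAX and IER3 did not pass with the compared groups fitted alone (0.0996 to 0.114), nor did IER3, ITGAX and CD40 with thinned reads (0.0687 to 0.280). ITGAX, TNFAIP3, IER3 and MYC did not pass with voom (0.0525 to 0.163). Without the level filter, the median was 0.073 for immediate-early genes. With thinned reads, the median was 0.16 for immediate-early genes.

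The CD5 marker, listed with T cell genes, was lower with sgKLHL14 under ibrutinib at -0.49 (limma adjusted p = 0.0317). Further lists passed by smaller margins, namely MAPK output (median 0.18, camera adjusted p = 0.0206; adjusted p = 0.182 with estimated correlation), STAT3 response (median 0.043, camera adjusted p = 0.0206; adjusted p = 0.274 with estimated correlation), MHC class I (median 0.098, camera adjusted p = 0.00131; adjusted p = 0.184 with estimated correlation), BCL2-family (median 0.079, camera adjusted p = 0.0172; adjusted p = 0.134 with estimated correlation), p53 target (median 0.042, camera adjusted p = 0.0218; adjusted p = 0.260 with estimated correlation), ribosome biogenesis (median 0.058, camera adjusted p = 0.0143; adjusted p = 0.274 with estimated correlation), ribosomal protein (median 0.070, camera adjusted p = 0.00150; adjusted p = 0.491 with estimated correlation) and cholesterol genes (median -0.060, camera adjusted p = 0.0206; adjusted p = 0.298 with estimated correlation). CD5 and the MAPK output and cholesterol lists lost the call without sgCTRL ibrutinib replicate 1 (adjusted p = 0.0534 to 0.241). CD5 and the STAT3 response and p53 target lists lost it without replicate 2 (0.0664 to 0.184). CD5 and the BCL2-family, p53 target, ribosome biogenesis, ribosomal protein and STAT3 response lists lost it without sgKLHL14 ibrutinib replicate 1 (0.0768 to 0.631). The cholesterol and MAPK output lists lost it without replicate 2 (0.0613 to 0.139). MAPK output genes had a median of 0.046 without sgCTRL ibrutinib replicate 1. STAT3 response genes had a median of 0.088 without sgCTRL ibrutinib replicate 2 and 0.14 without sgKLHL14 ibrutinib replicate 2. BCL2-family genes had a median of 0.042 without sgKLHL14 ibrutinib replicate 1. p53 target genes had a median of 0.11 without sgCTRL ibrutinib replicate 1, 0.064 without replicate 2 and 0.12 without sgKLHL14 ibrutinib replicate 2. Ribosomal protein genes had a median of 0.021 without sgKLHL14 ibrutinib replicate 1 and 0.12 without replicate 2. CD5 and the BCL2-family list did not pass without the level filter (0.0768 to 0.130), nor did CD5 without the variance trend (0.111) and with thinned reads (0.0627). The ribosomal protein list did not pass with quantile scaling (0.131). Without the level filter, the median was 0.094 for STAT3 response genes. With quantile scaling, the median was 0.028 for ribosomal protein genes. With thinned reads, medians were 0.019 for STAT3 response, 0.011 for p53 target and 0.035 for ribosome biogenesis genes.

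Differences between the guides recurred in both treatments. Of the genes higher with sgKLHL14, 70 were higher in DMSO and in ibrutinib, where independent lists of these sizes would share 1.6, and of those lower 48 were shared, against 0.9. Differences correlated across the 12533 genes at a Pearson coefficient of 0.366 and a Spearman coefficient of 0.332, and genes are not independent replicates. Of the 386 genes called in either treatment 92.8% had the same sign. The comparisons share no library.

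**Figure D4:**
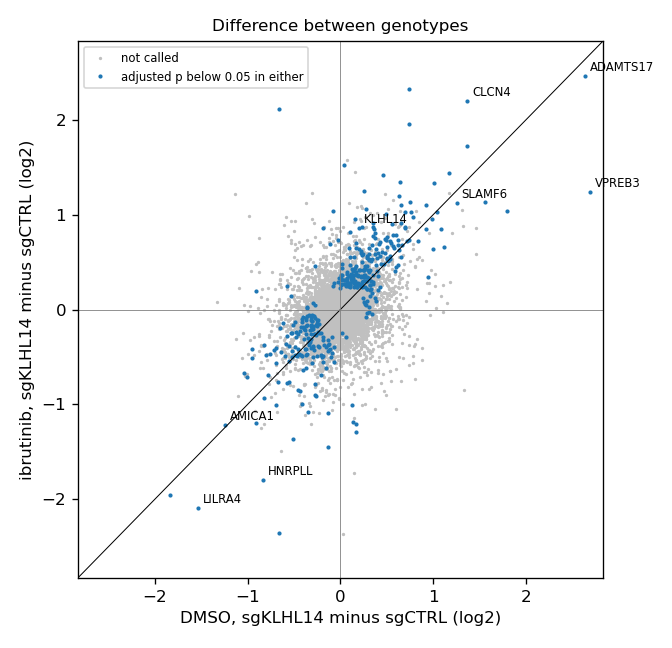
Log2 difference between sgKLHL14 and sgCTRL in DMSO (horizontal axis) against ibrutinib (vertical axis) for each of 12533 genes, with the 386 genes called in either treatment in blue. Among these 92.8% lie on the same side of 0 in both treatments.

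The last comparison asks whether ibrutinib acted differently with the guides. By limma, 3 of 12533 genes passed, KLHL14 and CLCN4 with a higher and HNRPLL with a lower response in the libraries labelled sgKLHL14, and 713 had an unadjusted p under 0.05. KLHL14 rose with ibrutinib by 0.90 with sgKLHL14 and by 0.24 with sgCTRL, a difference of 0.66 (SE 0.085, adjusted p = 0.00164). CLCN4 fell with sgCTRL (-1.02) and did not pass with sgKLHL14 (-0.18, adjusted p = 0.145), a difference of 0.84 (SE 0.13, adjusted p = 0.0235), on 118 to 1007 reads per library. HNRPLL changed by -0.91 with sgCTRL and by -1.87 with sgKLHL14, a difference of -0.96 (SE 0.12, adjusted p = 0.00137), on 116 to 1443 reads. Next by p-value were C1orf38 at 0.71 (SE 0.13, adjusted p = 0.105) and SLAMF7 at 0.52 (SE 0.10, adjusted p = 0.188). Without the level filter or without the variance trend, 0 genes passed by limma (1045 and 733 at an unadjusted p under 0.05), against 2 by voom on recovered reads, where CLCN4 did not pass (adjusted p = 0.096). C1orf38 passed with reads thinned to the shallowest library (adjusted p = 0.0348). The call of CLCN4 ended without sgCTRL DMSO replicate 1 (adjusted p = 0.121) or 2 (0.168), sgKLHL14 DMSO replicate 1 (0.174), sgCTRL ibrutinib replicate 1 (0.142) and sgKLHL14 ibrutinib replicate 1 (0.0838) or 2 (0.253).

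Responses of cell cycle genes to ibrutinib were lower in the libraries labelled sgKLHL14 as lists. The median difference in response was -0.16 for 28 G2/M genes (camera adjusted p = 1.17e-13, held with an estimated correlation, adjusted p = 0.0297) and -0.18 for 28 S phase genes (camera adjusted p = 6.34e-16; adjusted p = 0.0555 with estimated correlation). By limma, and by voom, 0 of these genes passed over all genes, 1 and 7 were lower adjusted over the list alone, and 9 and 12 were lower at an unadjusted p under 0.05. The smallest p-values belonged to the replication licensing gene MCM2 at -0.37 (SE 0.086, adjusted p = 0.385) and the mitotic activator CDC20 at -0.35 (SE 0.096, adjusted p = 0.481). Plasma cell genes had a median difference of 0.21 with 8 of 20 higher adjusted over the list alone, 8 at an unadjusted p under 0.05 and 0 over all genes by limma and by voom (camera adjusted p = 1.48e-07; adjusted p = 0.0555 with estimated correlation). Interferon-stimulated genes had a median of -0.13, with MX1 (-0.37) and IFI44L (-1.14) the smallest p-values, 0 of 31 called by limma and by voom over all genes and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00266; adjusted p = 0.105 with estimated correlation). Interferon-stimulated genes had a median of -0.074 without sgCTRL ibrutinib replicate 1.

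A rotation test did not separate the guides in the size of the whole response. Among the 3388 genes that rose with ibrutinib averaged over guides, the median change was 0.34 with sgCTRL and 0.37 with sgKLHL14, 42.3% had the smaller change with sgKLHL14, and the median difference was 0.028 (quartiles -0.075 and 0.13, adjusted p = 0.253 over both directions by fry, a 2-sided rotation test in limma). Among the 3178 genes that fell, the medians were -0.29 and -0.33, 42.5% changed less with sgKLHL14, and the median difference was -0.024 (quartiles -0.12 and 0.066, adjusted p = 0.253). Without sgKLHL14 ibrutinib replicate 1 both passed, with medians of 0.063 (adjusted p = 0.00336) and -0.057 (adjusted p = 0.0177).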

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

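The tests of scaling and depth, of exchanged labels, of single libraries and of drift were chosen only after the result was seen. All results here are differences between the guides in the response to ibrutinib, by limma's interaction test or by camera on it, apart from the genes shared by both treatments.

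KLHL14 mRNA responded more to ibrutinib in the libraries labelled sgKLHL14, by 0.66 (adjusted p = 0.00164), and stood above sgCTRL under ibrutinib. The smallest of its differences under ibrutinib over 4 scalings was 0.84 (SE 0.06), which argues against scaling or depth as the cause. The median of its 20 measured neighbours was 0.006 (SE 0.049 over those genes, not between libraries), which argues against a copy gain of the region. Genotype labels exchanged in both treatments would put KLHL14 higher under the label sgKLHL14 in both, and the smaller of the differences, 0.20 in DMSO, leaves this open because no other value tells the genotypes apart. A response of the KLHL14 locus to the edit itself is a candidate explanation that was not tested.

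The responses of the 56 cell cycle genes were lower in the libraries labelled sgKLHL14, with a median difference of -0.17 (SE 0.014) and 56 of 56 below 0, and medians of -0.18 for the S phase and -0.16 for the G2/M list. The weakest median over 3 scalings was -0.16 (SE 0.014), after regression on GC content and length it was -0.19 (SE 0.014), and with each library left out the weakest was -0.17 (SE 0.016), which argues against these causes of the whole pattern. The bounds of these tests were set with the medians known. A stronger slowing of division by ibrutinib in the cells labelled sgKLHL14 may account for it and was not tested, and the exchanged labels above would turn the direction.

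The 118 genes called in both treatments all differed the same way between the guides. Chromosome regions of changed copy number would place such genes side by side, yet 5.08% had another within 2 measured positions (upper 95% bound 10.7%; 106 of 1000 permutations were as large), which argues against that cause for most of them. Drift or selection between populations grown apart is a candidate explanation that stays open, because the libraries hold 1 guide against KLHL14, and so does a biological effect of the guide.

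CLCN4 had a response higher by 0.84 and HNRPLL one of -0.96 with sgKLHL14. The call of CLCN4 ended without sgCTRL DMSO replicate 1 (adjusted p = 0.121) or 2 (0.168), without sgKLHL14 DMSO replicate 1 (0.174), without sgCTRL ibrutinib replicate 1 (0.142) and without sgKLHL14 ibrutinib replicate 1 (0.0838) or 2 (0.253). Median differences of response were 0.21 for plasma cell, 0.19 for immediate-early, 0.11 for BCL2-family and 0.10 for STAT3 response genes. They were 0.070 for endoplasmic reticulum stress, 0.064 for adhesion, 0.057 for NF-kB target, 0.046 for MHC class II and 0.042 for amino acid response genes, and 0.034 for KLHL14 and cullin-3 partners. They were -0.13 for interferon-stimulated and -0.14 for histone genes and -1.14 for the pair of myeloid markers, which rest on few reads. With an estimated correlation the call of the G2/M list held and those of the other lists did not (adjusted p = 0.0555 to 0.336). The MHC class II, BCL2-family, STAT3 response and NF-kB target lists lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.0534 to 0.0849). The amino acid response, KLHL14 and cullin-3 partner, histone, myeloid marker, immediate-early, BCL2-family, endoplasmic reticulum stress and MHC class II lists lost it without replicate 2 (0.0530 to 0.143). The MHC class II list lost it without sgCTRL ibrutinib replicate 1 (0.0720). The KLHL14 and cullin-3 partner, myeloid marker, immediate-early, BCL2-family, STAT3 response, NF-kB target, MHC class II and amino acid response lists lost it without replicate 2 (0.0546 to 0.170). The myeloid marker, immediate-early, BCL2-family, STAT3 response, endoplasmic reticulum stress, NF-kB target, MHC class II and amino acid response lists lost it without sgKLHL14 DMSO replicate 2 (0.0843 to 0.512). The endoplasmic reticulum stress, NF-kB target, MHC class II, amino acid response, KLHL14 and cullin-3 partner, myeloid marker, immediate-early, BCL2-family and STAT3 response lists lost it without sgKLHL14 ibrutinib replicate 1 (0.114 to 0.549). The histone and MHC class II lists lost it without replicate 2 (0.0546 to 0.0990). Immediate-early genes had a median of 0.10 without sgCTRL DMSO replicate 1, 0.096 without replicate 2, 0.11 without sgKLHL14 DMSO replicate 2 and 0.077 without sgKLHL14 ibrutinib replicate 1. BCL2-family genes had a median of 0.055 without sgKLHL14 DMSO replicate 2. STAT3 response genes had a median of 0.054 without sgCTRL DMSO replicate 1, 0.16 without sgKLHL14 DMSO replicate 1 and 0.036 without replicate 2. Endoplasmic reticulum stress genes had a median of 0.037 without sgKLHL14 DMSO replicate 2. Adhesion genes had a median of 0.13 without sgCTRL DMSO replicate 2, 0.11 without sgKLHL14 DMSO replicate 1 and 0.024 without replicate 2. NF-kB target genes had a median of 0.034 without sgCTRL DMSO replicate 1 and 0.030 without sgKLHL14 DMSO replicate 2. MHC class II genes had a median of 0.029 without sgCTRL DMSO replicate 1, 0.086 without replicate 2, 0.12 without sgKLHL14 DMSO replicate 1, -0.0075 without replicate 2, 0.073 without sgCTRL ibrutinib replicate 1 and 0.024 without sgKLHL14 ibrutinib replicate 2. Amino acid response genes had a median of 0.070 without sgCTRL DMSO replicate 1, 0.022 without replicate 2, 0.070 without sgKLHL14 DMSO replicate 1, 0.065 without sgCTRL ibrutinib replicate 1, 0.0073 without replicate 2, 0.020 without sgKLHL14 ibrutinib replicate 1 and 0.080 without replicate 2. KLHL14 and cullin-3 partner genes had a median of 0.074 without sgCTRL DMSO replicate 1, 0.094 without sgKLHL14 DMSO replicate 2, 0.11 without sgCTRL ibrutinib replicate 1 and 0.11 without sgKLHL14 ibrutinib replicate 2. Interferon-stimulated genes had a median of -0.074 without sgCTRL ibrutinib replicate 1. Histone genes had a median of -0.27 without sgCTRL DMSO replicate 1, -0.059 without replicate 2 and -0.24 without sgKLHL14 DMSO replicate 2. Myeloid marker genes had a median of -0.47 without sgKLHL14 ibrutinib replicate 1 and -1.81 without replicate 2. The amino acid response, histone, myeloid marker, immediate-early and BCL2-family lists did not pass without the level filter (0.0808 to 0.313). The myeloid marker and BCL2-family lists did not pass with quantile scaling (0.0633 to 0.0666), nor did the BCL2-family, myeloid marker and immediate-early lists with thinned reads (0.0958 to 0.162). Without the level filter, medians were 0.065 for immediate-early and -0.74 for myeloid marker genes. With quantile scaling, medians were 0.077 for MHC class II and 0.054 for KLHL14 and cullin-3 partner genes. With thinned reads, medians were 0.049 for immediate-early, 0.073 for BCL2-family, 0.16 for STAT3 response, 0.10 for adhesion, 0.096 for NF-kB target, 0.073 for amino acid response, 0.072 for KLHL14 and cullin-3 partner and -0.28 for histone genes.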

How the results depend on the processing

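Among counts of genes, 108 values under the alternatives lay within 1.5 times the reported count and 22 did not. With at least 1.5-fold required, counts were 1339 and 1475 for ibrutinib with sgCTRL and sgKLHL14, 1489 over both, 58 for the guides in DMSO and 112 in ibrutinib, fewer by construction. Without the filter, the guides differed in 47 genes in DMSO and 155 in ibrutinib and the response in 0 by limma (1045 at an unadjusted p under 0.05), and without the trend in 25, 95 and 0 (733 unadjusted), where the cause was not tested. Voom called 2 genes for the response and thinned reads 4. Replicate numbers did not pair the libraries (correlations of deviations -0.056 to 0.12), and with the replicate block the guides differed in 368 genes in DMSO, the response in 5 (822 unadjusted). With a library left out, counts ran from 2902 to 4631 (ibrutinib, sgCTRL), 3561 to 4942 (sgKLHL14), 64 to 530 (guides in DMSO), 123 to 363 (in ibrutinib), 2 to 4 (response) and 5672 to 6309 (both guides), and the median differences in response size from 0.009 to 0.0628 and from -0.057 to -0.0035, fewer samples being the construction. Gene lists kept direction and side of the threshold in 998 cases, lost the call in 165, gained it in 9 and turned the direction of the test in 4, all of the myeloid markers (medians -0.0625, -0.2897, 0.0567 and 0.0567, in a range of -0.2897 to 0.4033 with a library left out), and named genes in 5373, 380, 2 and 2, the last BTK between the guides in DMSO (0.0065 without sgCTRL DMSO replicate 1, 0.005 without sgKLHL14 DMSO replicate 1). Medians alone turned for myeloid markers (-0.0276) and BCL2-family genes (-0.0248) with quantile scaling, and without a library for the latter (-0.0128, -0.0102) and MHC class II genes in the response (-0.0075). The cause of these was not tested. Depth limits the genes of few reads, and the unequal depths raise false calls between the guides in ibrutinib to 7.53%. Voom and thinning were chosen after seeing the data.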

Other observations

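All groups of genes here were chosen after their values were seen, while the test of other splits of the libraries was set before its result was seen.

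Ibrutinib changed many surface antigens that antibodies or engineered T cells target. Of 24 measured, 13 rose and 6 fell with sgCTRL and 14 rose and 5 fell with sgKLHL14 (limma). Increases with sgCTRL included CD52 (2.33), CD38 (1.54), CD27 (1.48), CD79B (1.24) and CD37 (1.04), and MS4A1 (0.45), which encodes CD20. Decreases included CD274 (-1.60) and SLAMF7 (-1.58). Genes higher in the libraries labelled sgKLHL14 included TNFRSF13C (0.69) and SLAMF7 (0.35) in DMSO and CD27 (1.01), TNFRSF13C (0.88) and SLAMF7 (0.87) in ibrutinib, where TNFRSF13C is a receptor for BAFF. Between the guides SLAMF7 lost the call without sgCTRL DMSO replicate 1 (adjusted p = 0.270). CD27 lost it without sgCTRL ibrutinib replicate 1 (0.0820). SLAMF7 lost it without sgKLHL14 DMSO replicate 1 (0.139). CD27 lost it without sgKLHL14 ibrutinib replicate 2 (0.0788). CD27 and SLAMF7 did not pass between the guides without the level filter (0.0904 to 0.0925), nor did SLAMF7, CD27 and TNFRSF13C without the variance trend (0.0725 to 0.166).

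Secreted cytokines and chemokines fell in 11 of 16 measured cases with either guide. With sgCTRL and sgKLHL14, IL6 changed by -2.87 and -2.49, IL10 by -2.50 and -2.51, CXCL10 by -2.02 and -1.21, and TNF by -1.52 and -1.06. LTB rose by 2.20 and 2.21 and IL16 by 0.82 and 0.93. Of 20 cytosolic aminoacyl-tRNA synthetases 14 fell with sgCTRL and 15 with sgKLHL14, among them WARS (-1.50 and -1.15), CARS (-1.39 and -1.19), GARS (-0.996 and -0.86) and YARS (-0.90 and -0.86). Some of these, such as WARS, also belong to the amino acid response list.

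In a fit of 4 against 4 libraries the split by ibrutinib called 5927 genes, the highest other 15, and 1 of 35 splits, the real one, gave as many. The other splits put both treatments in each arm, so the ibrutinib effect widens their spread and their low counts do not measure chance. Libraries of a group may be technical repeats, so chance differences between cultures are not excluded.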
